A study of Homo sapiens with 12 samples.

How the data were processed

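The series profiled transcripts of 2 subclones of CEM, an established human line from a T cell acute lymphoblastic leukaemia, on Affymetrix HG-U133_Plus_2 arrays. CEM C7-14 descends from a glucocorticoid-sensitive clone and CEM C1-15 from a resistant one, per the series' design text. Per the labels' protocols, cells in log growth were placed as 3 independent cultures per condition and received dexamethasone, a synthetic glucocorticoid, dissolved in ethanol, or ethanol alone. The dexamethasone concentration is written in the labels as 10E-6 M and is left in that notation, because it can be read in more than one way. RNA was extracted 3 h after the addition with a Qiagen kit and labelled with biotin by an ENZO transcriptional kit, per the labels' protocols. The 12 arrays fall into 4 groups of 3, and each array was placed in its group by the title in its label.

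The deposited values are intensities on a linear scale, with 1 value for each of 54675 probe sets on every array. The software that made these intensities from the scans is not given in the sources used here, and the series holds no raw scan files. The deposited intensities hold no value at or below 0, and the mean after trimming 2% at each end is 500.1 on all 12 arrays, which is what global scaling to one target leaves. That scaling was kept, by a rule that applied to linear tables whose trimmed means match within 5%. No detection call accompanies the intensities, so it is unknown whether a low intensity lies above background, and large folds against a low group depend on the offset. No pair of arrays held identical values.

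Values were analysed as log2(intensity + 20.3), where the offset of 20.3 is the 20th percentile of all pooled intensities. Fold changes are on that scale, which understates the change of dim transcripts. Probe sets with a mean log2 value below the 40th percentile, 6.44, were left out. The platform annotation supplied for the arrays gave 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777. The Entrez identifier of 41043 of the 1-symbol probe sets was found in a RefSeq gene table, which changed 0 symbols. Coordinates of that table are not printed because no source names a build for these files. Of the 25970 one-symbol probe sets kept, the one with the highest mean over the 12 arrays stood for its gene, which left 14032 genes. Where other kept probe sets of a named gene went another way, the text says so for the cases that change a reading. The 5548 kept probe sets without a symbol and the 1231 with several were tested apart.

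Each gene was fitted with limma version 3.58.1 in R version 4.3.3 as a model of 4 group means over all 12 arrays, with empirical Bayes moderation and an intensity trend in the prior variance. The 4 contrasts were the dexamethasone response in CEM C7-14, the same in CEM C1-15, the difference of those responses, and CEM C7-14 minus CEM C1-15 in ethanol. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 14032 genes of a comparison, and a gene was called at an adjusted p below 0.05. Errors of log2 changes are the moderated SE of that fit, and errors of intensities are SD over n = 3 arrays. The number of arrays limits the precision.

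The scale, filter, tests and naming rule, and 21 gene lists with 380 genes from textbook knowledge, were fixed before the data were examined, and 299 of these genes were measured. The lists cover glucocorticoid-induced genes, pro-apoptotic and anti-apoptotic BCL2 family members, ribosome biogenesis and MYC targets, G1/S and G2/M cell cycle genes, CDK inhibitors, cholesterol biosynthesis, glycolysis, immediate early and MAPK feedback genes, NF-kappaB targets, T cell receptor and surface genes, thymocyte and recombination genes, Notch receptors, ligands and targets, T-ALL oncogenes, markers of other cell types, ATF4 and unfolded protein response genes, heat shock genes, interferon-response genes, p53 targets, and the glucocorticoid receptor with its chaperones and cofactors. The 20 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over these 20 lists per comparison, and again with an estimated correlation. The anti-apoptotic list had 3 measured genes and was not tested as a list.

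The naming rule takes, for each comparison, the 10 largest increases and the 10 largest decreases among called genes whose 3 arrays of one group all lie beyond all 3 of the other, and for the difference in response among called genes. It adds from each list up to 4 called members with the smallest p, or the single member with the smallest p where none was called, and in every comparison NR3C1, FKBP5, TSC22D3, BCL2L11, BMF, BCL2, MYC and PFKFB2. List members named beyond that rule were chosen after their values were seen.

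The pipeline was tested on simulated data built from each gene's mean and its spread within groups, with 200 of 14032 genes changed. At a log2 size of 1, 70% of the changed genes were called for the response in CEM C7-14, 72% for the response in CEM C1-15, 52% for the difference in response and 74% between clones. At a log2 size of 0.5 these shares were 30%, 38%, 10% and 36%. The simulation called 153, 159, 124 and 166 genes in these comparisons, and the data 36, 10, 6 and 4382. The p-value needed for a call depends on that number, so the shares do not give the sensitivity reached in the data. Unchanged genes made up 3.92%, 3.77%, 4.84% and 7.83% of the genes called, the last, between clones, being 13 of 166 and above the 5% that the threshold aims at. In a simulated list test, 1 planted list was called and 0 of 20 random lists. Genes were simulated independently of each other, so this does not test false calls of lists whose genes are correlated. Control probe sets for transcript integrity and spiked RNA were compared between groups with exact permutation tests.

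Replicate numbers appear in the titles of all 4 groups. The labels do not say that a number marks a shared culture, day or batch, and the numbers were not treated as pairs. Alternatives covered quantile normalization, median centring, the offset, the filter, the handling of several probe sets per gene, the variance model, array weights, a fit on the compared groups alone, the replicate number as a block, each array left out in turn, and, chosen after seeing the data, the level of the poly-A spike-in RNA as a covariate.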

Results

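Transcript levels were measured on 12 arrays from 2 subclones of the human leukaemia line CEM, 3 h after dexamethasone or ethanol, with 3 independent cultures per group. CEM C7-14 is the glucocorticoid-sensitive subclone and CEM C1-15 the resistant one. Arrays of one group correlated with r from 0.974 to 0.986 across genes, and arrays of different clones with r from 0.933 to 0.945. The first principal component held 56.5% of the variance and separated the clones. The root mean square SD of a gene's log2 value within a group was 0.247 and 0.298 in ethanol-treated and dexamethasone-treated CEM C1-15, and 0.281 and 0.311 in the same groups of CEM C7-14.

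The first comparison asks which transcripts had changed 3 h after dexamethasone in the sensitive clone. TSC22D3, which encodes the glucocorticoid-induced leucine zipper, rose from an intensity of 85.5 ± 34.6 to 562 ± 72.3 (SD, n = 3). The transcription factor gene RUNX2 rose from 641.5 ± 84.3 to 3361 ± 99.3, and BTG1, an antiproliferative gene, rose by 2.23 ± 0.10 on the log2 scale. NR3C1, which encodes the glucocorticoid receptor itself, rose from 3755 ± 309 to 9663 ± 196.9, a log2 change of 1.36 ± 0.07. In all, limma called 30 genes higher and 6 lower among 14032, and in all 36 the 3 arrays of one group lay beyond all 3 of the other. A call with 3 arrays per group favours such separation, so this is not separate support. Over all genes the groups lay apart in this way for 11.4%, where chance gives 10%. With array weights 40 genes were higher and 28 lower, and after median centring 24 and 2.

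The members of the glucocorticoid-induced list made up the largest block of these calls. Of its 26 measured genes, 12 rose and 0 fell, or 17 and 0 when adjusted over the list alone, and the median log2 change was 0.62. They included DDIT4, an inhibitor of mTORC1 signalling (1.59 ± 0.09), PFKFB2, a regulator of glycolytic flux (1.58 ± 0.18), KLF13 (1.30 ± 0.09) and FKBP5, a cochaperone of the receptor (1.07 ± 0.07, from 3731 to 7842). SOCS1, IL7R, RCAN1, SLA and TXNIP were the other members called, with log2 changes of 1.09, 0.90, 0.73, 0.70 and 0.55. The list as a whole was shifted upwards by camera with an adjusted p of 4.52e-33, and with an adjusted p of 0.000307 with an estimated correlation. BCL6, SGK1, SIK1 and ZBTB16 had negative values, and none of these passed the test.

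Beyond that list, TNFSF8, which encodes the CD30 ligand, rose by 1.82 ± 0.20, SMIM3 by 1.34 ± 0.12 and the activation marker CD69 by 1.29 ± 0.12. When probe sets were averaged, TNFSF8 stood at 1.17 and lost its call (adjusted p = 0.103), while RUNX2 at 1.39 and TSC22D3 at 1.40 were still called. CD69 was the single called gene among the 20 measured members of the T cell receptor and surface list, whose shift was not called (adjusted p = 0.197, or 0.0210 when probe sets of a gene were averaged and up to 0.648 in other alternatives). The 6 genes that fell were PLXDC1 (-1.72 ± 0.31), the LIM-domain gene FHL2 (-1.62 ± 0.23), the tRNA modification gene YRDC (-0.61 ± 0.07), ZFAND1 (-0.52 ± 0.10), B3GNT2 (-0.48 ± 0.09) and MZT1 (-0.47 ± 0.07). FHL2 went from an intensity of 135 to 30.4 and PLXDC1 from 267 to 64.7, levels for which no detection call exists. PLXDC1, ZFAND1 and B3GNT2 each lost their call with any of 5 of the C7-14 arrays left out; the array that did not end it was ethanol replicate 1 for PLXDC1 and ZFAND1 and dexamethasone replicate 3 for B3GNT2. Over all alternatives PLXDC1 lost it in 9 of 19, ZFAND1 in 13 of 20 and B3GNT2 in 11 of 20. Without ethanol replicate 2, the adjusted p of these genes was 0.197, 0.277 and 0.211. YRDC and MZT1 lost theirs after median centring or when probe sets were averaged, and FHL2 when the CEM C1-15 arrays were left out. PLXDC1 also lost it when probe sets were averaged (-0.68). The count of lower genes ranged from 3 without C7-14 ethanol replicate 2 or dexamethasone replicate 2 to 11 without ethanol replicate 3 and 12 without dexamethasone replicate 3.

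No measured gene of the BCL2 family lists passed the test over all genes at 3 h. BCL2L11, which encodes the pro-apoptotic protein BIM, went from 775 to 1076, a log2 change of 0.46 ± 0.10 with an adjusted p of 0.0639. All 6 of its probe sets had a positive value, and it passed after quantile normalization (adjusted p = 0.0270) and with array weights (adjusted p = 0.0379), with a range up to 0.466 over 20 alternatives. BMF had a value of 0.33 ± 0.40, BCL2 of -0.05 ± 0.13 and BCL2L1 of -0.14 ± 0.12. The pro-apoptotic list had 0 of 9 members called and an adjusted p of 0.443. Adjusted over the list alone, 1 was higher, BCL2L11, and 1 lower, PMAIP1 (-0.24). Of the anti-apoptotic list, 0 of 3 measured members were called.

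MYC, at an intensity of 11462 in ethanol, had a log2 change of -0.11 ± 0.08 (adjusted p = 0.779), and the ribosome biogenesis list, with NIP7 at -0.32 ± 0.08 as its leading member, had 0 of 20 members called (adjusted p = 0.897). For MEF2C, a transcription factor of T cell leukaemia, the value was -0.44 ± 0.09 (adjusted p = 0.0559), for NOTCH1 -0.49 ± 0.11 (adjusted p = 0.0976) and for TNF -0.62 ± 0.15 (adjusted p = 0.150). MEF2C passed in 6 of 20 alternatives, with an adjusted p of 0.0277 without C7-14 ethanol replicate 3 and 0.0154 without dexamethasone replicate 3, and TNF passed at 0.0125 without dexamethasone replicate 1. The G2/M list shifted upwards by a median of 0.08 with 0 of 19 members called. Its adjusted p of 0.00122 became 0.303 with an estimated correlation, 0.308 after quantile normalization and 0.0516 without C7-14 dexamethasone replicate 1. The leading members of the remaining uncalled lists were MCM3 (0.22), CDKN2D (-0.38), STARD4 (-0.46), PKM (0.18), JUN (0.43), RAG1 (-0.41), NKG7 (0.69), ATF5 (0.36), STIP1 (0.35), IFITM2 (0.23) and DDB2 (0.37), all with 0 members called in their lists. Adjusted over the list alone, the NF-kappaB list had 1 higher, NFKBIA (0.68), and 2 lower, TNF and NFKB2, and the Notch list 1 higher, JAG1 (0.78), and 2 lower, NOTCH1 and HES1. Also on that basis 1 member was lower in each of 5 lists, namely NIP7, CDKN2D, STARD4, RAG1 and MEF2C. In the list of the receptor with its cofactors, NR3C1 was the single called member of 12.

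**Figure D1:**
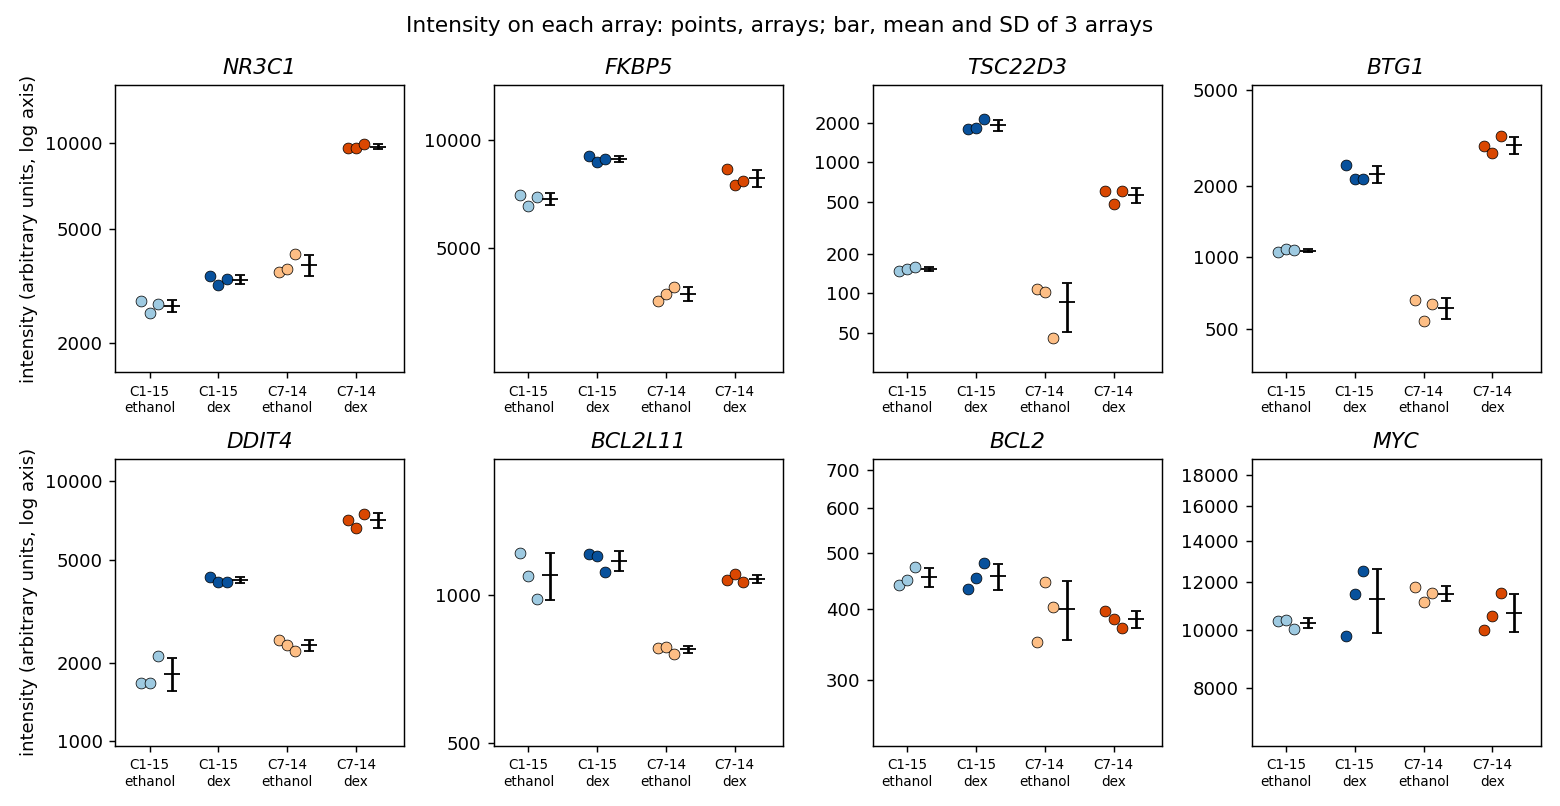
Intensity on a log axis of 8 genes on each of the 12 arrays, by clone and treatment; points are arrays and the bar beside them is the mean with SD of 3 arrays. NR3C1 lies at 9663 in dexamethasone-treated CEM C7-14 and at 3329 in dexamethasone-treated CEM C1-15, while TSC22D3 lies at 562 and 1919 in the same groups.

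The second comparison puts the same question to the resistant clone. In CEM C1-15 TSC22D3 rose from 154 ± 6.1 to 1919 ± 189.5 (SD, n = 3), a log2 change of 3.47 ± 0.21. DDIT4 rose by 1.19 ± 0.09, BTG1 by 1.04 ± 0.10, SMIM3 by 0.74 ± 0.12 and KLF13 by 0.73 ± 0.09. ZFP36L2, an mRNA decay factor, rose by 0.65 ± 0.08, SMAP2 by 0.63 ± 0.10 and the integrin gene ITGA6 by 0.55 ± 0.07. These 8 genes also rose in CEM C7-14, where lists of 30 and 10 drawn independently would share 0.0214 genes. The other 2 calls were the non-coding transcript CIBAR1-DT (1.67 ± 0.27, from 55.7 to 217.9) and TSPO, a mitochondrial outer membrane protein (0.67 ± 0.11). With limma, 10 genes were higher and 0 lower, and 1107 genes had an unadjusted p below 0.05 in either direction, against 1060 in CEM C7-14. The 3 arrays of one treatment lay beyond all 3 of the other for 14.0% of genes, where chance gives 10%. With array weights 47 genes were higher and 22 lower, whereas 4 were higher after median centring and 3 with no variance trend. The count of higher genes was 16 without C1-15 dexamethasone replicate 1 and 6 without dexamethasone replicate 2. Without dexamethasone replicate 2, 3 genes were lower. CIBAR1-DT, SMIM3, SMAP2 and TSPO lost their call in 8, 11, 9 and 12 of 20 alternatives, 4, 6, 5 and 6 of them fits with 1 array left out. The highest adjusted p among the fits without 1 array was 0.178, 0.230, 0.111 and 0.214, without dexamethasone replicate 3 for CIBAR1-DT and SMIM3, ethanol replicate 1 for SMAP2 and ethanol replicate 3 for TSPO. KLF13 lost its call in 4 of 20 alternatives (adjusted p up to 0.333), ITGA6 in 3 (up to 0.188) and ZFP36L2 in 2 (up to 0.0838), median centring and the fit without a variance trend among them for all 3. TSC22D3, DDIT4 and BTG1 lost theirs in 0 of 20.

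Among the 26 measured glucocorticoid-induced genes, 4 rose in CEM C1-15 and 0 fell, or 14 and 0 when adjusted over the list alone. The median log2 change was 0.28 and the camera test gave an adjusted p of 7.33e-14, or 0.00699 with an estimated correlation. In the same arrays the 18S ribosomal RNA probe set was lower after dexamethasone, with a log2 difference of -0.58, and the difference between 3 prime and 5 prime GAPDH probe sets was higher by 0.0516, each with all 3 arrays of one treatment beyond the other (exact permutation p = 0.1, the smallest possible, and 0.25 after Benjamini-Hochberg adjustment). FKBP5, which was already at 6869 in ethanol, had a log2 change of 0.37 ± 0.07 with an adjusted p of 0.0533, which lay below the threshold in 6 of 20 alternatives (0.00913 with array weights) and reached 0.773 in others. For NR3C1 the value was 0.30 ± 0.07 (adjusted p = 0.249, or 0.0441 with array weights, the lowest of 20 alternatives). Of its 5 probe sets 4 had a positive value, 1 of these was called when each probe set was tested on its own, and the values ran from -0.59 to 0.48. PFKFB2 had a value of 0.47 ± 0.18 (adjusted p = 0.567). BCL2L11 stood at 0.10 ± 0.10, MYC at 0.13 ± 0.08, BCL2 at 0.00 ± 0.13, and BMF, with an SE of 0.40, at 94.0 in ethanol and 103.1 in dexamethasone.

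The glycolysis list shifted upwards by a median of 0.14 in CEM C1-15, with 18 of 20 members positive and 0 called. LDHA led it with 0.17 ± 0.06. Its adjusted p of 0.00750 became 0.361 with an estimated correlation and lay between 0.0594 and 0.306 in 6 other alternatives, which included quantile normalization and the fits without C1-15 dexamethasone replicate 1 (0.0594) or replicate 3 (0.0956). In the other lists of this comparison 0 members were called and the lowest adjusted p was 0.124, shared by the G2/M list and the markers of other cell types. Without C1-15 dexamethasone replicate 2 the G2/M list passed, with a median of 0.11 and an adjusted p of 0.00324. CD69 passed without C1-15 ethanol replicate 2 (0.70, adjusted p = 0.025). The leading members were PLK1 (0.45), CD79A (0.58), CD69 (0.56), IFIT3 (1.37 ± 0.46), DUSP10 (0.53), CD34 (0.52), PHLDA3 (0.51), SLC3A2 (0.34), MVK (0.31), HSP90AB1 (0.22), NOP2 (0.20), BCL2L1 (0.18), MYB (0.08), PMAIP1 (-0.15), CDT1 (-0.25), CDKN2D (-0.26), CREBBP (-0.32), JAG1 (-0.35) and TNF (-0.74 ± 0.15). For the NF-kappaB list the median of 0.14 and the mean of 0.03 were positive while the test pointed down (adjusted p = 0.838).

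**Figure D2:**
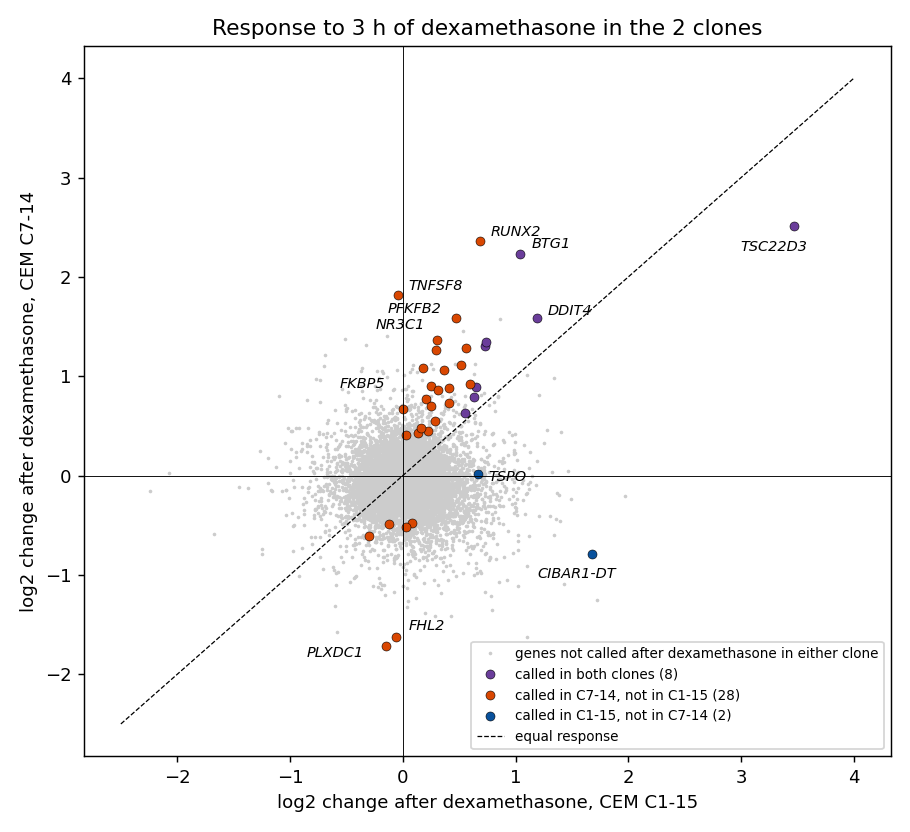
Log2 change after dexamethasone in CEM C7-14 (vertical axis) against that in CEM C1-15 (horizontal axis) for 14032 genes, with genes called in either clone coloured and the dashed line marking equal responses. Of the 30 genes raised in CEM C7-14, 29 lie above the dashed line, and TSC22D3 lies below it.

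The third comparison tests whether the response differed between the clones. With limma 5 genes had the larger log2 response in CEM C7-14 and 1 differed in the opposite direction, whereas with array weights 7 and 11 genes did. TNFSF8 rose in CEM C7-14 from 242 to 905 and stood at 46.9 and 44.9 in CEM C1-15, a difference of 1.86 ± 0.28 in log2 response (adjusted p = 0.0197). No detection call exists for these CEM C1-15 levels. Whether TNFSF8 was expressed there at all is unknown. RUNX2 differed by 1.68 ± 0.21 (adjusted p = 0.00315), BTG1 by 1.19 ± 0.14 (adjusted p = 0.00199), NR3C1 by 1.06 ± 0.10 (adjusted p = 0.000377) and FKBP5 by 0.70 ± 0.09 (adjusted p = 0.00509). RUNX2 was dim in CEM C1-15, at 81.3 to 126.1 in ethanol and 165.1 to 195.3 in dexamethasone. FKBP5 ended higher in treated CEM C1-15 (8681 to 9059) than in treated CEM C7-14 (7502 to 8321). Its ethanol level was also higher in CEM C1-15, at 6579 to 7059 against 3564 to 3904. For CIBAR1-DT, which rose in CEM C1-15 and had a value of -0.79 in CEM C7-14, the difference was -2.46 ± 0.38 (adjusted p = 0.0225).

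The glucocorticoid-induced list was shifted as a whole. Its median difference was 0.25, 21 of 26 members had the larger log2 change in CEM C7-14, and 3 were called higher and 0 lower, or 9 and 1 when adjusted over the list alone. The camera test gave an adjusted p of 9.01e-09, and 0.0309 with an estimated correlation. TSC22D3 was the member with the largest fold in either clone and its value was the other way, at -0.96 ± 0.30 with an adjusted p of 0.562. Without C7-14 ethanol replicate 3, where its intensity was 45.8 against 108.9 and 101.8 on the other 2 arrays, that value was -1.27 with an adjusted p of 0.0465. PFKFB2 differed by 1.11 ± 0.25 (adjusted p = 0.282), CD69 by 0.72 ± 0.16 (adjusted p = 0.282) and BCL2L11 by 0.36 ± 0.13 (adjusted p = 0.642), none of them past the threshold. MYC stood at -0.23 ± 0.11, BMF at 0.33 ± 0.57 and BCL2 at -0.06 ± 0.18. No other list was called, and the lowest adjusted p among them was 0.324, for the CDK inhibitors. The leading members of the other lists were JAG1 (1.13), IRF7 (1.10), CDKN2A (0.65), STIP1 (0.54), DUSP6 (0.42), CDC20 (0.36), NOP2 (-0.31), CCNE2 (-0.32), BCL2L1 (-0.32), MEF2C (-0.37), ENO2 (-0.38), SESN1 (-0.41), SLC7A11 (-0.51), RAG1 (-0.53), CD79A (-0.57), MVK (-0.57) and NFKB2 (-0.97), none of them called. MVK passed without C1-15 dexamethasone replicate 1 (-0.69, adjusted p = 0.0452), and without that array 10 genes were lower in place of 1.

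The poly-A spike-in RNA, a control added to each RNA sample, moved in opposite directions with dexamethasone in the clones. Its mean log2 level was higher by 0.38 in dexamethasone-treated CEM C1-15 (exact permutation p = 0.1, the smallest that 3 against 3 allows) and lower in dexamethasone-treated CEM C7-14, with a difference of -0.29 (exact permutation p = 0.3). With that level as a covariate, an alternative chosen after seeing the data, 0 genes were called for the difference in response with limma, and 553 had an unadjusted p below 0.05 against 1000 without it. NR3C1 then differed by 0.96 ± 0.14 (adjusted p = 0.0850), RUNX2 by 1.82 ± 0.29 (adjusted p = 0.112) and BTG1 by 1.15 ± 0.19 (adjusted p = 0.143), and the glucocorticoid-induced list stayed past the threshold with a median of 0.21. The ATF4 and unfolded protein response list passed in that fit alone, with a median of 0.15 and an adjusted p of 0.0360 against a range up to 0.951. TNFSF8 lost its call in 14 of 24 alternatives and CIBAR1-DT in 13 of 25, 9 and 9 of them fits with 1 array left out, with an adjusted p of up to 0.106 in these, without C7-14 dexamethasone replicate 2 for both. RUNX2 (0.93, adjusted p = 0.519) and FKBP5 (0.61, adjusted p = 0.0606) lost theirs when probe sets were averaged, and FKBP5 also after median centring (0.78, adjusted p = 0.343), with no variance trend (0.70, adjusted p = 0.108) and with the poly-A covariate (0.62, adjusted p = 0.573).

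Across all 14032 genes, nearly all of them uncalled in either clone, Pearson's r of the responses was -0.0135 and Spearman's rho -0.00709. Over the 36 genes called in CEM C7-14, Pearson's r was 0.624. Genes are not independent replicates, and the responses share no arrays. Among the 30 genes raised in CEM C7-14, 29 had a positive value in CEM C1-15, with a median of 0.91 in the first and 0.39 in the second. Choosing genes by their call in one clone raises that clone's median. Of the 10 genes raised in CEM C1-15, 9 were positive in CEM C7-14, with a median of 0.73 in CEM C1-15 and 1.10 in CEM C7-14, and 3, TSC22D3, CIBAR1-DT and TSPO, had the larger value in CEM C1-15.

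**Figure D3:**
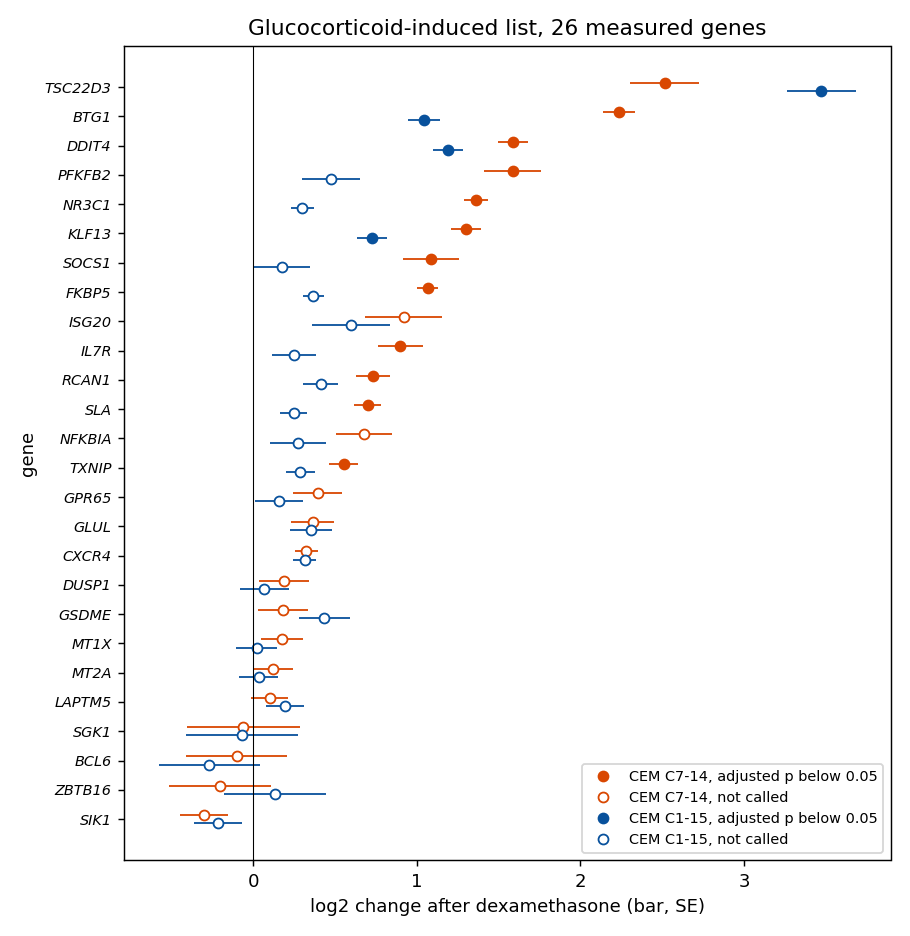
Log2 change after dexamethasone with its SE (horizontal axis) for the 26 measured genes of the glucocorticoid-induced list (vertical axis) in each clone; filled points were called. The medians are 0.62 in CEM C7-14 and 0.28 in CEM C1-15, and 21 of the genes have the larger value in CEM C7-14.

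The last comparison sets the clones against each other without hormone. They differed far more from each other than either did after dexamethasone: 2127 genes were higher in CEM C7-14 and 2255 lower, 31.2% of those tested, with 410 and 492 at least 2-fold apart. The 3 arrays of one clone lay beyond all 3 of the other for 49.2% of genes, where chance gives 10%. CEM C7-14 had NLGN4X at 7922 against 5.7 in CEM C1-15 (8.25 ± 0.20), EPAS1, which encodes hypoxia-inducible factor 2 alpha, at 7483 against 57.4 (6.64 ± 0.17), and TPD52 at 6056 against 91.8 (5.76 ± 0.12). CEM C1-15 had CTHRC1 at 5311 against 42.5 in CEM C7-14 (-6.48 ± 0.20), the tubulin gene TUBB6 at 6175 against 85.0 (-6.05 ± 0.42) and LIN28B, an inhibitor of let-7 microRNA maturation, at 5515 against 84.8 (-5.86 ± 0.26). Whether the lower level of such pairs lies above background is unknown. Clone and culture history cannot be told apart here.

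The next largest excesses in CEM C7-14 were those of PTPRK (5.56), FAM221A (4.64), the kinase gene PRKCA (4.57), DYNLT3 (4.49), ERI2 (4.19), DEPDC7 (4.14) and TCF4 (4.10). In CEM C1-15 they were those of RUNDC3B (-5.79), RASSF8 (-5.49), the phosphodiesterase gene PDE4D (-4.94), CCDC69 (-4.66), the chloride channel gene CFTR (-4.55) and DDC (-4.54), which encodes aromatic amino acid decarboxylase. ARHGEF12 had a value of -6.35 ± 0.16 on its brightest probe set, but 2 of its 3 probe sets had a positive value. Averaged over probe sets, ARHGEF12 stood at -1.97, RASSF8 at -1.87, PDE4D at -2.86 and ERI2 at 2.38. TCF4 stood at 1.67 with no offset, a fit in which another of its probe sets stood for the gene, so that value does not measure the offset. DEPDC7 stood at 2.73 with the larger offset, and all of these were still called.

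**Figure D4:**
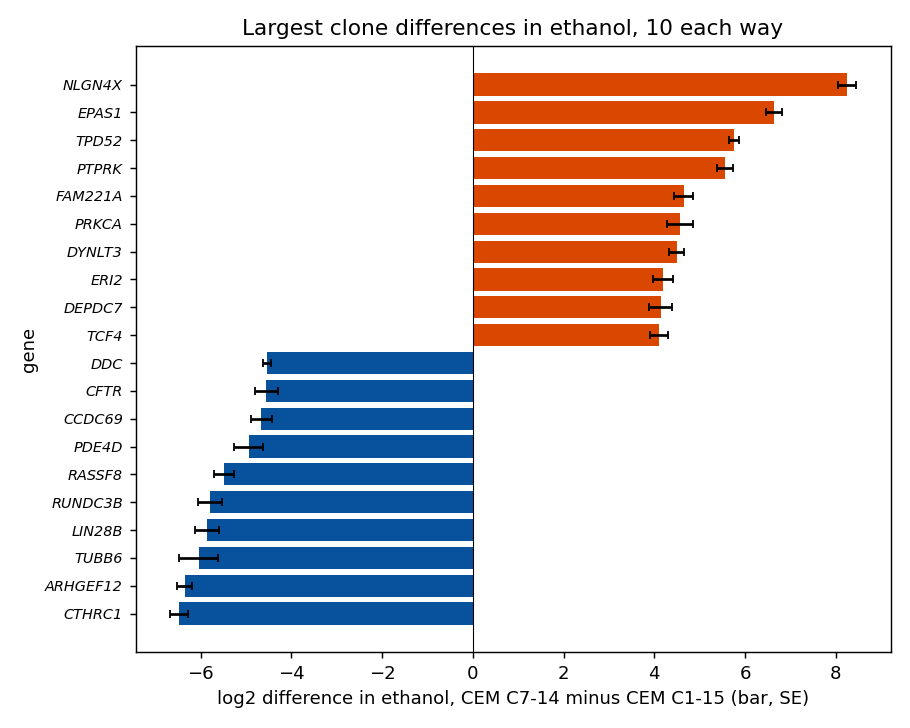
Log2 difference in ethanol between CEM C7-14 and CEM C1-15 with its SE (horizontal axis) for the 10 largest differences each way (vertical axis), n = 3 arrays per clone. The values run from 8.25 for NLGN4X to -6.48 for CTHRC1.

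In the thymocyte and recombination list 6 of 13 members were higher in CEM C7-14 and 5 lower. The antigen-presenting genes CD1D (3.24 ± 0.20) and CD1A (2.11 ± 0.10) and the surface enzyme gene CD38 (1.66 ± 0.10) were higher, whereas the recombinase gene RAG1 was lower (-2.92 ± 0.11, 1109 against 8489). In the T cell receptor and surface list 7 were higher and 4 lower. CD69 (0.81) and CD3D (0.49) were higher, and the costimulatory receptor gene CD28 (-3.15 ± 0.16) and CD247, the zeta chain of the receptor (-1.01 ± 0.09), were lower. Of 8 Notch receptors, ligands and targets 2 were higher and 4 lower, with DTX1 at 1.54 ± 0.20, the ligand gene JAG1 at -3.77 ± 0.20, HES4 at -2.14 ± 0.27 and HES1 at -1.16 ± 0.11. JAG1 ran from -4.25 to -2.43 over 19 alternatives and lost its call in 0. Of 9 T-ALL oncogenes 2 were higher, LMO2 (0.39) and TAL1 (0.31), and 3 lower, ERG (-2.70 ± 0.21) and MEF2C (-0.77 ± 0.09) among them. LMO2 lost its call without C1-15 ethanol replicate 1 or 3 or C7-14 ethanol replicate 2 (adjusted p = 0.0565, 0.0769 and 0.0869), and TAL1 without C1-15 ethanol replicate 3 or C7-14 ethanol replicate 2 (0.0547 and 0.0583) and when probe sets were averaged (0.14, adjusted p = 0.365).

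The glucocorticoid-induced list had 7 members higher and 9 lower in ethanol, or 8 and 11 when adjusted over the list alone (adjusted p = 0.588). GLUL, glutamine synthetase, stood at 10442 in CEM C7-14 and 698 in CEM C1-15 (3.89 ± 0.13), and SLA was higher by 0.79 ± 0.08. TXNIP (-2.24 ± 0.09), FKBP5 (-0.88 ± 0.07) and TSC22D3 (-0.78 ± 0.21) were lower in CEM C7-14, the last without its call when probe sets were averaged or the other groups left out. The receptor gene NR3C1 was higher by 0.47 ± 0.07 (3755 against 2699, adjusted p = 0.000146). After median centring its value was 0.26 with an adjusted p of 0.183. The drug efflux gene ABCB1 was lower (-1.06 ± 0.28), as were STIP1 (-0.52 ± 0.12) and EP300 (-0.26 ± 0.08), and the list of the receptor with its cofactors had 2 members higher and 4 lower. EP300 lost its call without C1-15 ethanol replicate 3 or C7-14 ethanol replicate 1 or 2 (adjusted p = 0.0783, 0.0541 and 0.0652), after quantile normalization (0.0579) and with the poly-A covariate (0.188).

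In the pro-apoptotic list 0 of 9 members were higher and 2 lower, BCL2L11 (-0.48 ± 0.10) and BID (-0.45 ± 0.11). Of the 6 probe sets of BCL2L11, 3 had a negative value, and its mean over probe sets was -0.10 with an adjusted p of 0.561. BID lost its call with the poly-A spike-in level as a covariate (-0.30, adjusted p = 0.14). BCL2 stood at -0.18 ± 0.13 (adjusted p = 0.288) and BMF at 0.07 ± 0.40, and of the anti-apoptotic list 0 of 3 were called. MYC did not pass (0.16 ± 0.08, adjusted p = 0.144), and PFKFB2 neither (-0.43 ± 0.18, adjusted p = 0.0764, or 0.0214 after quantile normalization and up to 0.530 in other alternatives).

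Cholesterol biosynthesis had 7 of 16 members higher and 0 lower, with SREBF2 (0.74 ± 0.12), the sterol sensor gene INSIG1 (0.63 ± 0.09), LSS (0.61 ± 0.12) and HMGCS1 (0.43 ± 0.08). The list had a median of 0.20 and an adjusted p of 0.113, which was 0.0287 after quantile normalization and up to 0.717 in other alternatives, and its median was -0.01 after median centring. Glycolysis had 6 of 20 higher and 4 lower, among them the muscle phosphofructokinase gene PFKM (-3.02 ± 0.13), ENO2 (-0.78), HK1 (-0.66) and GPI (-0.59). The ATF4 and unfolded protein response list had 2 of 17 higher and 6 lower, with ATF4 (-0.38), HSPA5 (-0.53), CEBPB (-0.55) and HERPUD1 (-0.74) (adjusted p = 0.113). Of 12 heat shock genes 3 were higher, BAG3 (0.96) and HSPB1 (0.95) among them, and 3 lower. CHORDC1 (-0.24) was one of these. It had a value of 0.03 when probe sets were averaged and lost its call with any of 5 arrays left out, C7-14 ethanol replicate 3 being the array that did not end it, with an adjusted p of up to 0.0744, without C1-15 ethanol replicate 1.

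Among 5 CDK inhibitors 0 were higher and 2 lower, CDKN1B (-0.66 ± 0.08) and CDKN2D (-0.36 ± 0.10), with a list adjusted p of 0.113. The G1/S list had 4 of 23 higher and 2 lower, with E2F1 at 0.95 ± 0.21, MCM5 at 0.28, CDC25A at -0.38 and CCND3 at -0.42. The G2/M list had 2 of 19 higher and 5 lower, with BUB1B at 0.59, CCNB2 at -0.31 and CENPF at -0.48. AURKB (-0.38 ± 0.08) had a second probe set called in the opposite direction, and the mean over its probe sets was 0.50. CDKN2D lost its call without C1-15 ethanol replicate 1 or 2 or C7-14 ethanol replicate 2, with an adjusted p of 0.0705, 0.0638 and 0.0610, and MCM5 without C1-15 ethanol replicate 1 (0.0710). With the poly-A covariate CDKN2D (0.0939), MCM5 (0.0894) and AURKB (0.0877) also lost theirs. Ribosome biogenesis genes had 2 of 20 higher, with NOP2 at 0.48, and 4 lower, with RRP9 at -0.71, RRP12 at -0.59 and TFB2M at -0.34. Averaged over probe sets, RRP12 was -0.09, CENPF -0.23 and CCNB2 -0.21, and none of these passed.

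Among 20 immediate early and MAPK feedback genes 5 were higher, with JUN at 2.19 ± 0.14 and ETV5 at 0.91 ± 0.10, and 5 lower, with DUSP1 at -1.32 ± 0.15 and ATF3 at -1.08 ± 0.12, which was -0.12 and not called when probe sets were averaged. DUSP1 ran from -1.53 to -0.56 over 19 alternatives and lost its call in 0. NF-kappaB targets had 3 of 11 higher, with NFKB1 and TNF both at 0.98, and 2 lower, NFKBIA (-0.69) and TNFAIP3 (-0.32). TNFAIP3 lost its call without C1-15 ethanol replicate 1 or 2 or C7-14 ethanol replicate 3, with an adjusted p of 0.0707, 0.0542 and 0.0715. NFKBIA lost its call with the poly-A spike-in level as a covariate (-0.30, adjusted p = 0.280). Interferon-response genes had 5 of 16 higher, with OAS3 at 1.25 and ISG15 at 0.49, and 3 lower, with IFITM2 at -0.78 and IFITM3 at -0.54. P53 targets had 2 of 13 higher, FAS (0.64) and XPC (0.54), and 3 lower, TP53I3 (-1.69 ± 0.21) and ZMAT3 (-0.73 ± 0.13) among them. Markers of other cell types had 4 of 14 higher, with CD79A at 1.37, EPCAM at 1.02 and ALAS2 at 0.86, and 1 lower, NKG7 at -3.02 ± 0.24. ALAS2 lost its call with any of 5 arrays left out, C7-14 ethanol replicate 2 being the array that did not end it, and had an adjusted p of up to 0.0943, without C7-14 ethanol replicate 1. With camera 0 of the 20 lists were called between the clones, and the lowest adjusted p was 0.113. The median and the test pointed apart for G2/M genes (0.01, test down), immediate early genes (0.00, test down) and heat shock genes (-0.02, test up), and the glycolysis mean was -0.10 with a median of 0.16.

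The balance of these calls depended on the scaling. Under the authors' scaling 48.5% of the called genes were higher in CEM C7-14 and the median log2 difference of all genes was 0.08. After centring each array on its median, 768 genes were higher and 2941 lower, so that 20.7% were higher, and the median of all genes was -0.13. CD3D, HMGCS1, ISG15, LMO2, MCM5, NOP2, NR3C1, TAL1, XPC and ALAS2 were then no longer called. With the poly-A covariate LMO2, TAL1, TNFAIP3, CHORDC1 and ALAS2 were not called either, and after quantile normalization CHORDC1 and ALAS2 were not. That covariate left 1091 genes higher and 1597 lower. The mean poly-A spike-in level in ethanol was 8.46 in CEM C7-14 and 7.99 in CEM C1-15, a difference that was not tested. All 3 CEM C7-14 arrays lay above all 3 CEM C1-15 arrays, the nearest at 8.07 and 8.06. Spike-in level and clone therefore cannot be fully told apart in ethanol. CHORDC1 was not called with no variance trend. The log2 difference between the 3 prime and 5 prime ACTB control probe sets, a measure of transcript integrity, was 0.707 ± 0.103 in CEM C7-14 and 0.566 ± 0.0831 in CEM C1-15 (SD, n = 6, exact permutation p = 0.0281, 0.25 after Benjamini-Hochberg adjustment over 15 tests). The level of an 18S ribosomal RNA probe set was lower in CEM C7-14, with a difference of -0.52 (exact permutation p = 0.0346, adjusted 0.25, n = 6). Both tests include the dexamethasone-treated arrays. In ethanol alone, which was not tested, the mean ACTB difference was 0.743 in CEM C7-14 and 0.544 in CEM C1-15. The mean 18S level in ethanol was 12.05 in CEM C7-14 and 12.86 in CEM C1-15.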

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

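The tests of the array spread and of chromosome copy number, and the fit with the poly-A spike-in level, were chosen only after the results were seen. Under a test of the difference itself, 6 genes and 1 list responded differently in the clones. The differences in log2 response, CEM C7-14 minus CEM C1-15, were 1.06 for NR3C1, 1.19 for BTG1, 1.68 for RUNX2, 0.70 for FKBP5, 1.86 for TNFSF8 and -2.46 for CIBAR1-DT, and the median of the glucocorticoid-induced list was 0.25. FKBP5 nevertheless ended higher in treated CEM C1-15 than in treated CEM C7-14. For TNFSF8 it is unknown whether its low CEM C1-15 levels lay above background. Outside the gene tests, 1 of the 1231 probe sets that carry several gene symbols had a log2 change of -0.75 ± 0.13 after dexamethasone in CEM C7-14 with an adjusted p of 0.0466.

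The first pattern is the smaller response of CEM C1-15 to dexamethasone in the glucocorticoid-induced list and in the genes raised in CEM C7-14. With limma 10 genes were called in CEM C1-15 against 36 in CEM C7-14. An unadjusted p below 0.05, however, held for 1107 genes in CEM C1-15 and 1060 in CEM C7-14. The SD of the log2 changes over all genes was 0.252 and 0.250, so a smaller response over all genes was not seen. A larger spread between its arrays is argued against, since the root mean square SD within groups over the 26 list genes was 0.170 in CEM C1-15 and 0.242 in CEM C7-14. With each array left out in turn it ran from 0.155 to 0.182 and from 0.227 to 0.261. A ceiling of the scale is argued against. Of the 30 genes raised in CEM C7-14, 0 had an ethanol level in CEM C1-15 above 14486, which is 50% of the lowest array maximum. The highest stood at 10871. A lower starting level in CEM C1-15 cannot be told apart from the alternatives: over the 26 list genes the Spearman correlation of the ethanol difference with the response difference was -0.30 (permutation p = 0.136), and because both share the ethanol arrays, simulated equal responses gave a mean of -0.10 with a central 95% range from -0.46 to 0.30 when the clone differences were kept, and of -0.66 with a range from -0.87 to -0.35 without them. Over the 30 genes raised in CEM C7-14, chosen for that call, the correlation was -0.01 (permutation p = 0.941). The simulated ranges rest on assumed settings, so they decide nothing. In ethanol the list as a set was not lower in CEM C1-15. There 9 members were called higher and 7 lower than in CEM C7-14, and the median difference, CEM C7-14 minus CEM C1-15, was -0.16. The poly-A covariate ended the calls of single genes chiefly through their error, since NR3C1 went from 1.06 ± 0.10 to 0.96 ± 0.14 and the SE of a typical gene grew 1.37 times, so a part played by RNA input stays open, beside the clones' biological difference, which no test here isolates.

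Regrouping the arrays does not exclude chance for the count behind that pattern. Of 100 splits of dexamethasone and ethanol arrays within the clones, the labelled one included, 6 gave at least the 6 genes called, and the highest other count was 35. All 5 of the other splits kept the CEM C7-14 arrays parted as labelled, and the one with 35 also parted CEM C1-15 as labelled but with its treatments exchanged, which adds the responses in place of subtracting them. Of the 85 splits that mixed both clones, the highest count was 2. The larger counts therefore came from splits that held the CEM C7-14 response intact, a structure of the samples.

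The second pattern is that the resistant clone responded at all. A candidate technical explanation is that some CEM C7-14 cells were present in the dexamethasone-treated CEM C1-15 cultures. The 20 genes with the largest excess in CEM C7-14 gave a median share of 0.184% of CEM C7-14 signal in those arrays, with an SD of 3.11 over genes and a maximum of 8.07%. The 10 raised genes would have needed a median share of 62.7% and at least 28.2%, and TSC22D3 ended at 1919, above the 562 of treated CEM C7-14 itself. The tables thus argue against such an admixture as the cause, while the rise of TSC22D3, DDIT4 and BTG1 kept its call in all 20 alternatives tried. That the rise arose in the CEM C1-15 cells themselves is a biological explanation, held as a hypothesis because it was weighed on the data that showed it.

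For the 3 comparisons of 2 groups, the 6 arrays allow 10 splits, too few for a share under 0.05. Every split other than the labelled one also mixes the groups, so a real difference enters the error and lowers the count. Low counts in those splits are therefore no support for the calls. For dexamethasone in CEM C7-14, 1 of 10 splits gave as many genes as the labelled one, which gave 36 against at most 1 in the others. For dexamethasone in CEM C1-15 it was 1 of 10, with 10 genes against at most 2, and between clones 1 of 10, with 4382 against at most 0.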

How the results depend on the processing

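The fit with the poly-A spike-in level was chosen only after the data were seen. Called named genes kept direction and call in 1587 comparisons with alternatives other than leaving out an array, lost the call in 102 and turned sign in 2, CHORDC1 (0.0322) and AURKB (0.50) between clones when probe sets were averaged. With 1 array left out 731 calls held and 79 were lost. Uncalled named genes passed in 25 and 6 cases, and 162 uncalled values changed sign. The glucocorticoid-induced list stayed past the threshold in 19 alternatives for each response (medians 0.44 to 0.70 in CEM C7-14 and 0.22 to 0.33 in CEM C1-15) and 24 for the difference (0.21 to 0.34, adjusted p at most 0.0309). Genes lower after dexamethasone in CEM C7-14 numbered 10 after quantile normalization, 2 after median centring, 10 with no offset, 3 with no filter, 28 with array weights, and 3 both with only the groups compared and with the poly-A covariate. Genes higher in CEM C1-15 numbered 4 after median centring, 3 with no variance trend, 47 with array weights and 4 with the poly-A covariate, and genes lower 1 with no offset, 22 with array weights and 2 with only the groups compared. For the difference in response, genes lower numbered 4 with the offset at the 40th percentile, 0 with no filter, 3 with the filter at the 60th percentile and 11 with array weights, against 7 higher in that fit, so that the balance turned. Genes higher numbered 2 when probe sets were averaged and 8 with every probe set on its own, and with the poly-A covariate limma called 0 higher and 0 lower, with 553 at an unadjusted p below 0.05. Between clones 768 genes were higher after median centring and 1091 with the poly-A covariate, and 3463 probe sets were higher and 3469 lower with every probe set on its own, where more features were tested. The correlation of the responses was 0.0948 with the filter at the 60th percentile and -0.213 with the poly-A covariate. With the replicate number as a block within clone, 27 genes were higher and 4 lower in CEM C7-14 and 7 higher in CEM C1-15, and with the block across clones 31 and 5, and 14 higher. Deviations of arrays with the same number correlated with r from -0.138 to 0.156, over 0.1 in 4 of 18 pairs. In 10 of 18 the array correlated best with its own number, and in 2 of 6 pairs of groups all 3 did. Both of these pairs joined ethanol-treated CEM C1-15 with a CEM C7-14 group. Between the treatments of CEM C7-14 no array correlated best with its own number (r = -0.138, 0.0111 and -0.0289). Between those of CEM C1-15 only replicate 2 did (r = 0.0689). The share expected by chance was not computed, so this is at most a hint from the data and not from the design. With 1 array left out, counts ran from 25 to 34 higher and 3 to 12 lower in CEM C7-14, from 6 to 16 and 0 to 3 in CEM C1-15, from 4 to 6 and 0 to 10 for the difference, and from 1418 to 1882 and 1792 to 2081 between clones, and the correlation from -0.101 to 0.0743. The list medians then ran from 0.54 to 0.64, 0.26 to 0.30, 0.23 to 0.31 and -0.23 to -0.11. The highest counts of 12, 16 and 10 came without C7-14 dexamethasone replicate 3, C1-15 dexamethasone replicate 1 and the same C1-15 array. Apart from the number of probe sets tested, the cause was not tested. Without detection calls, signal over background is unknown for dim transcripts.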

Other observations

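The test of chromosome copy number was chosen only after the clone differences were seen. A hypothesis for the many differences between the clones in ethanol is the gain or loss of whole chromosomes in one of them, which would move the genes of a chromosome together. Across 23 chromosomes with 13993 measured genes, the largest distance of a chromosome's median log2 difference from the median of all genes was 0.0723, below the bound of 0.3 set for this test, and chromosome medians ran from 0.01 to 0.13. A change from 2 to 3 copies would correspond to 0.58, and the gain of 1 copy from a higher starting number to less. The starting copy number was not measured. Chromosome medians include dim genes, whose changes the log offset understates. In 460 windows of 30 neighbouring genes brighter than an intensity of 500, window medians ran from -0.28 to 0.23. The tables argue against whole-chromosome changes as the cause of the clone differences, and losses or gains of short regions stay open.

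Probe sets without a gene symbol also separated the clones. Of 5548 such probe sets, 770 were called between the clones in ethanol, as were 314 of the 1231 with several symbols. In the same fit 7657 of all 32749 probe sets were called. The share was thus smaller among probe sets without a symbol, and among those with several symbols it was close to that of all. With limma 0 of the 5548 were called after dexamethasone in either clone or for the difference in response.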
